A study of Homo sapiens with 8 samples.

How the data were processed

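Gene expression was measured with Affymetrix HG-U133 Plus 2.0 arrays in 8 samples of the colon cancer cell lines DKS-5 and DKO-3. The labels describe DKS-5 as K-ras mutant and DKO-3 as K-ras wild-type. Each line was sampled at 21% O2 (normoxia) and after 12 h at 1% O2 (hypoxia), with 2 arrays in each of the 4 groups. Per the labels' protocols, total RNA was extracted with a column kit, amplified to cDNA with the NuGEN Ovation V2 system and labelled with biotin. Nothing in the sources used here says whether the 2 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

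The deposited values were probe set intensities on a linear scale for 54675 probe sets, made with MAS5 per the submitters' processing notes. The MAS5 version and target intensity were not given in the sources used here, and detection calls were not used here. The 2% trimmed means of the deposited intensities differed 1.52-fold between arrays. Under a rule set before the data were examined, with a tolerance of 10%, each array was therefore scaled to the median trimmed mean of 172.1. Values were then taken as log2(signal + 16), so that fold changes understate the change of dim genes. The 62 control probe sets were left out of the tests. The platform annotation listed 41091 probe sets with 1 gene symbol and 1801 with several genes, and 11721 further probe sets were unnamed here. Of the probe sets with 1 gene, 41037 matched a gene of the RefSeq table of assembly GRCh38.p14, and 0 symbols changed. That table was used only for names and for which genes neighbour each other, because no genome build is named for the arrays. Each of the 19775 genes with a probe set was represented by the probe set with the highest mean log2 value over all 8 arrays. Genes whose mean lay above the 40th percentile of all probe sets' means, a scaled signal of about 13.8, were tested, which left 12735 genes. The K-ras gene itself and some members of the gene lists are not analysed here.

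Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 8 arrays, contrasts, eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All 4 groups shared 1 estimate of the spread, with 4 residual and 11.3 prior degrees of freedom. The 5 comparisons were hypoxia against normoxia in DKS-5, the same in DKO-3, the difference between these responses (the interaction), and DKS-5 against DKO-3 in normoxia and in hypoxia. Overlap of the hypoxia calls between the lines was set against the product of the list sizes over the number of genes tested, with a one-sided Fisher's exact test.

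The designs, the alternatives and 20 gene lists with 378 genes were fixed before the data were examined, and 291 of those genes were tested. The lists were glycolysis, oxygen sensing and HIF feedback, angiogenic and vasoactive factors, other hypoxia-adaptation genes, collagen and lysyl modification, apoptosis regulators, ERK pathway output, EGFR ligands, proliferation, Wnt/beta-catenin targets, intestinal differentiation, epithelial junctions and keratins, mesenchymal genes, unfolded protein and integrated stress response, cholesterol synthesis, oxidative phosphorylation and citric acid cycle, ribosome biogenesis, NF-kappaB and chemokines, interferon response, and non-epithelial cell markers. Lists were tested with camera (limma, preset correlation 0.01), adjusted over the 20 lists of each comparison. The alternatives were camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way. The adjusted p with an estimated correlation was also larger for lists whose estimate lay below the preset value. It therefore does not measure correlation within a list alone. Per comparison, the named genes were the 10 largest rises and the 10 largest falls among genes past the threshold whose 2 groups' arrays did not overlap. For the interaction the rule was 5 and 5, with every array of one line's hypoxia difference beyond the other's. Where none passed, the 5 genes with the smallest p were named. Added to these were HIF1A, EPAS1, VEGFA and HRAS, among other fixed genes not analysed here, and up to 4 members of each list with the smallest p.

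The tests were checked on simulated log2 values with the means and spreads of the 12735 genes and 200 changed genes. The noise was drawn independently for each gene with the same spread in all groups. On the real arrays the SD of the log2 difference between replicates ran from 0.309 in DKS-5 normoxia to 0.465 in DKS-5 hypoxia. Unequal groups and correlated genes were thus not simulated, and the shares recovered may overstate those on the real arrays. For hypoxia in DKS-5, 60% of 2-fold and 100% of 4-fold changes were recovered with 8 false calls among 168. For hypoxia in DKO-3 the shares were 64% and 100%, for the lines in normoxia 62% and 100%, and for the lines in hypoxia 69% and 99%. For the interaction they were 25% and 98%, with 7 false calls among 130. These shares hold for 200 changed genes, because the adjustment is stricter where fewer genes change. For the interaction, with 0 calls on the real arrays, they do not say how often a lone 4-fold change would be found.

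Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, the mean of all probe sets of a gene, each probe set by itself, eBayes without trend or with a robust prior, a fit of only the 4 arrays compared, the replicate number as a block, a 2-fold minimum, and leaving out each array in turn. When an array was left out, the lone array of its group was assumed to vary like the other groups. Chosen after the data were seen were an RNA quality covariate (the mean log2 3' to 5' signal ratio of the ACTB and GAPDH control probe sets), no array scaling, and a closer look at the fit without DKS-5 hypoxia replicate 2. Figures were drawn with matplotlib 3.10.9.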

Results

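The arrays compared 2 colon cancer lines, DKS-5 (K-ras mutant per the labels) and DKO-3 (K-ras wild-type per the labels), at 21% O2 and after 12 h at 1% O2, with 2 arrays in each of 4 groups. The level of the K-ras gene itself is not analysed here, so the genotype labels were not checked against it. The 2% trimmed mean of the deposited signals ranged from 133 to 201 and was brought to 172.1 on every array. Across the 12735 genes tested, Pearson's r between arrays of a group was 0.989 for DKS-5 normoxia, 0.976 for DKS-5 hypoxia, 0.983 for DKO-3 normoxia and 0.983 for DKO-3 hypoxia. Some arrays of different groups were at least as alike. DKS-5 hypoxia replicate 1 had r = 0.986 with each DKS-5 normoxia array, above the 0.976 with its own replicate. DKO-3 normoxia replicate 2 and DKO-3 hypoxia replicate 2 had r = 0.9835, against 0.9828 and 0.9834 within the DKO-3 groups. Genes are not independent replicates. The first principal component held 38.6% of the variance and separated the lines, with scores from -24.0 to -18.6 in DKS-5 and from 13.4 to 33.1 in DKO-3. DKS-5 hypoxia replicate 2 lay farthest out on the second component, with a score of -33.0. No direct measure of RNA integrity was used here, and the 3' to 5' signal ratios of control probe sets stand for RNA quality. These ratios differed between and within groups. The ratio of ACTB was 55.1 and 34.3 in DKS-5 normoxia, 54.8 and 25.6 in DKS-5 hypoxia, 49.0 and 14.9 in DKO-3 normoxia, and 11.47 and 11.02 in DKO-3 hypoxia. The same ratio of GAPDH was 3.70, 4.23, 3.76, 2.36, 4.15, 2.09, 1.53 and 1.61 in that order. Of the 18 fixed non-epithelial cell markers, 2 (COL1A1 and HBB) were bright enough to be tested, and neither passed the threshold in any comparison.

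The first comparison asked which genes respond to low oxygen in the K-ras mutant line. In DKS-5, 12 h of hypoxia raised transcripts of sugar uptake and glycolysis and other classical hypoxia genes, along with some single genes of the HIF feedback loop and of vessel formation. NDRG1, a hypoxia-induced differentiation gene, rose by 3.82 ± 0.20 on the log2 scale (SE, 2 arrays per group), from a signal of 130 ± 3.47 to 2046 ± 71.4 (SD, n = 2; adjusted p = 7.33e-08). MIR210HG, the host transcript of the hypoxia-induced microRNA miR-210, rose 8.15-fold, and TMEM45A rose 6.42-fold. The order depended on the pseudocount: with 1 in place of 16, MIR210HG stood at 4.07, ANGPTL4 at 3.98 and NDRG1 at 3.97. The glucose transporter gene SLC2A3 rose 5.89-fold, the transcriptional repressor gene BHLHE40 5.88-fold, the mTOR inhibitor gene DDIT4 5.70-fold, CFAP96 5.52-fold, the enolase gene ENO2 5.33-fold, the prolyl hydroxylase gene EGLN3 5.08-fold and ANGPTL4 5.02-fold. VEGFA, the main vascular growth factor gene, rose by 2.12 ± 0.24 (adjusted p = 0.000206), and its 4 probe sets rose by between 1.04 and 2.12. In all, 64 of 12735 genes passed the threshold, 64 higher and 0 lower in hypoxia. Limma gave 569 higher and 313 lower genes at an unadjusted p under 0.05, where 637 in all would be met by chance.

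Among the fixed lists, glycolysis and the other hypoxia-adaptation genes rose most broadly in DKS-5. Of 20 glycolysis genes, 11 rose, 0 fell and 9 did not pass, and 16 rose when adjusted over the list alone. PFKFB3 rose by 1.78 and PFKFB4 by 2.19, both regulators of glycolytic flux (camera adjusted p = 1.93e-29, and adjusted p = 0.0259 with an estimated correlation). Of 23 other hypoxia-adaptation genes, 12 rose and 11 did not pass (14 adjusted over the list alone), with the mitophagy gene BNIP3L at 2.23 and the adenylate kinase gene AK4 at 2.16 (camera adjusted p = 7.48e-28, and adjusted p = 0.0259 with an estimated correlation). Of 11 genes of oxygen sensing and HIF feedback, 3 rose over all genes and over the list alone, namely BHLHE40, EGLN3 and EGLN1 (1.17), while HIF1A (-0.53, adjusted p = 0.632) and EPAS1 (0.26, adjusted p = 0.909) did not pass. That list's camera adjusted p was 0.000786, with adjusted p = 0.0754 with an estimated correlation. Of 11 angiogenic and vasoactive factors, 4 rose by either adjustment, ANGPTL4, VEGFA, ADM (1.90) and STC1 (1.71). The camera adjusted p was 4.42e-05, and adjusted p = 0.0663 with an estimated correlation. Of 9 genes of collagen and lysyl modification, 3 rose by either adjustment, P4HA1 (1.41), PLOD2 (1.36) and P4HA2 (1.06), although a dimmer P4HA1 probe set gave -0.03 (camera adjusted p = 2.42e-05, and adjusted p = 0.0754 with an estimated correlation). Fry called every list of this paragraph upward, with adjusted p from 0.00176 for other hypoxia-adaptation genes to 0.0316 for collagen and lysyl modification.

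Smaller shared shifts were seen in other groups. The 15 cholesterol synthesis genes all had positive values in DKS-5, with 0 past the threshold over all genes and 4 adjusted over the list alone. MSMO1 was at 0.76 (adjusted p = 0.0725). Camera gave that list adjusted p = 1.01e-08, and adjusted p = 0.0776 with an estimated correlation. Fry called it too (adjusted p = 0.0316). Of 17 epithelial junction and keratin genes, KRT19 alone rose, by 1.28, by either adjustment (camera adjusted p = 0.000724, and adjusted p = 0.180 with an estimated correlation). Fry did not call that list (adjusted p = 0.190). Camera placed ribosome biogenesis (median -0.28 over 17 genes, camera adjusted p = 0.00327, and adjusted p = 0.437 with an estimated correlation) and NF-kappaB and chemokines (median -0.16 over 13 genes, camera adjusted p = 0.0180, and adjusted p = 0.267 with an estimated correlation) lower than other genes. Fry called neither (adjusted p = 0.328 and 0.306), and no member of these last lists passed by either adjustment. The ribosome call ended without DKS-5 hypoxia replicate 2, and that of NF-kappaB and chemokines ended without array scaling and without replicate 1 of either DKS-5 group. RRS1 stood at -0.62 and CXCL1 at -0.84. In the remaining 11 lists the camera adjusted p was at least 0.1001. Their members past the threshold were SPRY1 (1.68, of 19 ERK pathway output genes; its other probe set gave -0.15) and VLDLR (1.42, of 18 genes of the unfolded protein and integrated stress response), and adjusted over the list alone 1 gene rose in each of these, 1 of 14 Wnt/beta-catenin targets and 2 of 9 mesenchymal genes. None passed among 20 apoptosis regulators, 4 EGFR ligands, 24 proliferation genes, 12 intestinal differentiation genes, 13 interferon response genes or 20 genes of oxidative phosphorylation and the citric acid cycle. The last list's median was 0.05 while camera placed it lower than other genes. The count of 64 became 35 without the filter on dim probe sets, 32 without array scaling and 36 in a fit of only the 4 arrays compared, and 29, 37, 294 and 40 without DKS-5 normoxia replicates 1 and 2 and DKS-5 hypoxia replicates 1 and 2. The 294 without DKS-5 hypoxia replicate 1 were 167 higher and 127 lower, and every other setting whose directions were counted gave 0 to 2 lower genes. The calls of EGLN1, STC1, P4HA2, KRT19, VLDLR and PLOD2 ended when 1 or more of the single arrays were left out, with adjusted p of up to 0.672. ANGPTL4, PFKFB4, P4HA1, P4HA2, SPRY1 and KRT19 did not pass with the mean of all their probe sets (1.13, 1.08, 0.69, 0.82, 0.77 and 1.36).

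**Figure D1:**
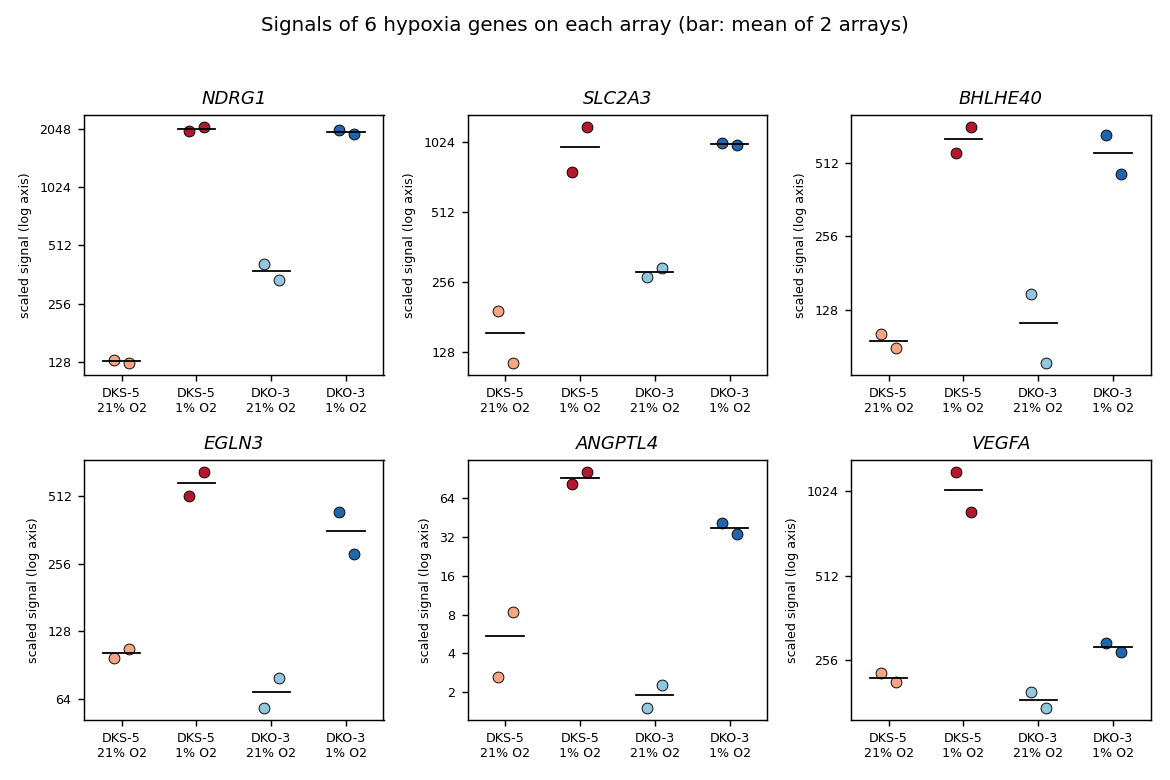
Scaled signal (log axis) of NDRG1, SLC2A3, BHLHE40, EGLN3, ANGPTL4 and VEGFA on each of the 8 arrays; points are arrays and lines are means of 2 arrays. VEGFA averaged 1032 in DKS-5 hypoxia and 285 in DKO-3 hypoxia, whereas NDRG1 averaged 2046 and 1969.

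The second comparison asked the same of the K-ras wild-type line. In DKO-3, hypoxia raised many of the same kinds of genes. MIR210HG rose by 2.41 ± 0.28 on the log2 scale (SE, 2 arrays per group; adjusted p = 0.000876), LOC154761 rose 5.12-fold, NDRG1 5.07-fold (from 377 ± 50.4 to 1969 ± 52.8, SD, n = 2) and the neuritin gene NRN1 4.67-fold. With a pseudocount of 1, ANGPTL4 stood at 3.73 and NRN1 at 3.60, above MIR210HG at 3.22. BHLHE40 rose 4.59-fold, EGLN3 4.37-fold, EFHD1 4.31-fold, PRR15L 4.08-fold, BNIP3L 3.76-fold and PPFIA4 3.67-fold. VEGFA was at 0.58 ± 0.24 (adjusted p = 0.415), with its 4 probe sets between 0.58 and 1.09. In all, 44 genes passed, 44 higher and 0 lower. At an unadjusted p under 0.05 limma gave 999 higher and 342 lower genes, and the other settings whose directions were counted gave 0 to 8 lower genes past the threshold.

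Of 20 glycolysis genes in DKO-3, 6 rose and 14 did not pass, and 18 rose when adjusted over the list alone. PFKFB4 rose by 1.70, SLC2A3 by 1.78, ALDOA by 1.39 and TPI1 by 1.15, although a dimmer TPI1 probe set gave -0.33 (camera adjusted p = 4.30e-18, and adjusted p = 0.0695 with an estimated correlation). Of 23 other hypoxia-adaptation genes, 9 rose (15 adjusted over the list alone), with AK4 at 1.47 and DDIT4 at 1.30 (camera adjusted p = 1.74e-16, and adjusted p = 0.0695 with an estimated correlation). Of 11 angiogenic and vasoactive factors, ANGPTL4 (1.57) rose and 3 did when adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.223 with an estimated correlation). ADM was at 1.06 (adjusted p = 0.0706). P4HA1 (1.04) and PLOD2 (1.02) rose among 9 genes of collagen and lysyl modification, 5 adjusted over the list alone (camera adjusted p = 0.00341, and adjusted p = 0.223 with an estimated correlation). The call of this list ended with the RNA quality covariate (camera adjusted p = 0.243), without DKO-3 normoxia replicate 1 and by fry (adjusted p = 0.0892). A dimmer P4HA1 probe set gave -0.45. The 15 cholesterol synthesis genes had 0 members past the threshold and 1 adjusted over the list alone, with LSS at 1.07 (camera adjusted p = 0.00339, and adjusted p = 0.364 with an estimated correlation). The calls of the cholesterol and angiogenic lists ended without DKO-3 normoxia replicate 2, that of the angiogenic list also without the filter, and that of cholesterol synthesis also by fry. Outside the called lists, EGLN3 and BHLHE40 rose among 11 genes of oxygen sensing and HIF feedback (4 adjusted over the list alone), and VLDLR (1.71) rose among 18 stress response genes (2 up and 1 down adjusted over the list alone). HIF1A (-0.47, adjusted p = 0.469) and EPAS1 (0.41, adjusted p = 0.626) did not pass. Fry called glycolysis (adjusted p = 0.00604), other hypoxia-adaptation genes (0.00501), angiogenic factors (0.0153) and oxygen sensing and HIF feedback (0.0153) upward in DKO-3.

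In the 15 lists that camera did not call in DKO-3 its adjusted p was 0.0516 or more. Apart from the genes just named none of their members passed over all genes. Adjusted over the list alone 1 Wnt/beta-catenin target, 2 intestinal differentiation genes, 1 epithelial gene (KRT19 was at 1.12) and 2 mesenchymal genes rose. For EGFR ligands, the stress response and NF-kappaB and chemokines the median and the mean had opposite signs. The 2 DKO-3 hypoxia arrays also had the lowest ACTB 3' to 5' ratios, 11.47 and 11.02, against 49.0 and 14.9 in DKO-3 normoxia. With the RNA quality covariate 8 genes passed in place of 44. The median log2 change of the 44 was 1.502 without and 1.541 with the covariate, and their median SE was 0.255 and 0.334. Of the named genes MIR210HG, NDRG1, NRN1, BHLHE40, BNIP3L and PPFIA4 kept their calls with the covariate, whereas the others did not, among them EGLN3 (1.79, adjusted p = 0.116), SLC2A3 (1.55, 0.323), ALDOA (0.97, 0.743) and DDIT4 (1.38, 0.0516). The count was also 7 without the filter, 84 without array scaling and 68 in a fit of 4 arrays, and without DKO-3 hypoxia replicate 1 it was 1 (NDRG1 alone of the named genes), without DKO-3 hypoxia replicate 2 22, without DKO-3 normoxia replicate 1 24 and without DKS-5 hypoxia replicate 2 69. The calls of ANGPTL4, P4HA1 and PLOD2 ended without any 1 of the 4 DKO-3 arrays. Those of SLC2A3, TPI1 and ALDOA ended without DKO-3 normoxia replicate 1 or either hypoxia replicate, and those of PPFIA4 and VLDLR without DKO-3 normoxia replicate 2 or hypoxia replicate 1. With the mean of all their probe sets ANGPTL4, PFKFB4, TPI1 and P4HA1 did not pass (0.81, 1.03, 0.63 and 0.29).

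Of the genes that rose, 31 rose past the threshold in both lines, where lists drawn independently would share 0.221 (one-sided Fisher's exact test, p = 4.23e-65; genes are not independent replicates, so the p describes these arrays). They included NDRG1, MIR210HG, BHLHE40, EGLN3, ANGPTL4, SLC2A3, PFKFB4 and VLDLR. The tests in the lines shared 1 spread estimate per gene, which by itself favours calls in common. The overlap was 7 without the filter and 6 with the RNA quality covariate. It was 1 without DKO-3 hypoxia replicate 1, 16 without DKO-3 hypoxia replicate 2, and 18 without DKS-5 normoxia replicate 1 or either DKO-3 normoxia replicate.

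**Figure D2:**
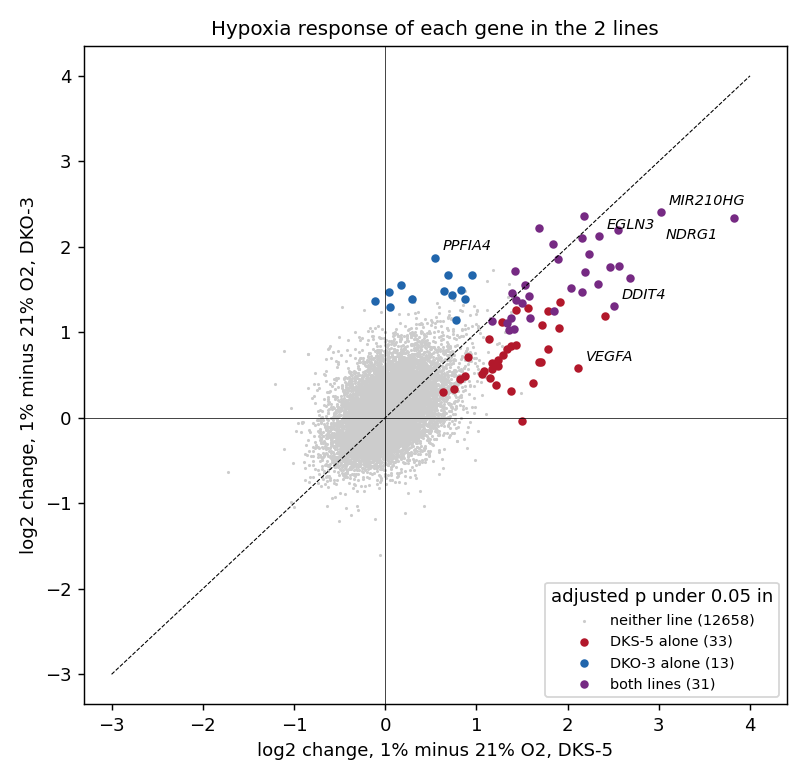
Log2 change from 21% to 1% O2 of each of the 12735 genes in DKS-5 (horizontal) and DKO-3 (vertical); colours mark genes past the threshold in both lines (31), in DKS-5 alone (33) or in DKO-3 alone (13), and the dashed line marks equal changes. NDRG1 lies at 3.82 and 2.34, VEGFA at 2.12 and 0.58.

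The third comparison asked whether the hypoxia response differed between the lines. No gene's response did so past the threshold. Camera placed the differences of 4 lists (glycolysis, angiogenic and vasoactive factors, other hypoxia-adaptation genes and ERK pathway output) toward DKS-5, each with adjusted p = 0.606 with an estimated correlation. ERK pathway output passed camera in neither line alone, with medians of 0.0024 in DKS-5 and -0.14 in DKO-3. The genes with the smallest p were DDIT4, whose rise was larger in DKS-5 by 1.21 ± 0.23, NDRG1 (1.48 ± 0.29), VEGFA (1.54 ± 0.33), the kisspeptin receptor gene KISS1R (1.54 ± 0.34) and ARLN (1.06 ± 0.24), none past the threshold (adjusted p of at least 0.738; SE, 2 arrays per group). The VEGFA difference was -0.04 to 1.54 across its 4 probe sets. NDRG1 began lower in DKS-5 in normoxia and reached near equal signals in the lines in hypoxia. Its larger rise thus came with a lower start, not with a clearly higher level in DKS-5 hypoxia. The brightest VEGFA probe set, by contrast, was higher in DKS-5 in hypoxia. Limma gave 0 genes in every setting run, and 333 at an unadjusted p under 0.05 where 637 would be met by chance. A count below chance says that the p-values of this comparison did not spread as chance alone would give. It is therefore no evidence that the responses were equal.

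By camera the difference had adjusted p = 0.0272 for glycolysis (13 of 20 genes larger in DKS-5, median difference 0.34, PFKFB3 at 0.97 and ENO2 at 1.22). The list's own rise in DKS-5 and DKO-3 had medians of 0.83 and 1.07 but means of 1.12 and 0.94. For angiogenic and vasoactive factors the medians were 0.07 and 0.20 and the means 0.70 and 0.42, so for both lists the sign of the difference depended on the summary. The medians of other hypoxia-adaptation genes were 1.08 and 0.75. Between the lines (DKS-5 minus DKO-3) that list had a median of -0.24 in normoxia and 0.0551 in hypoxia, so its difference lay mainly in normoxia. For the other lists called here the median between the lines was larger in hypoxia than in normoxia. The difference had adjusted p = 0.0291 for angiogenic and vasoactive factors (6 of 11 genes, median 0.05, with ADM at 0.84 and STC1 at 1.05), and 0.00243 for other hypoxia-adaptation genes (17 of 23, median 0.14, with TMEM45A at 1.04 and PPFIA4 the other way at -1.33). For ERK pathway output it was 0.0291 (12 of 19, median 0.16, with SPRY1 at 1.03 and IER3 at 0.47; another SPRY1 probe set gave -0.20). Each of the 4 had adjusted p = 0.606 with an estimated correlation, and fry called 0 of 20 lists one way and 2 when either direction counted. No member passed over all genes, and adjusted over the list alone 2 glycolysis genes, 1 angiogenic factor and 2 other hypoxia-adaptation genes were larger in DKS-5 and 1 of the latter was smaller. The other 16 lists had camera adjusted p of at least 0.141, and the list of proliferation genes had a median of -0.04 against an upward direction by camera. Quantile normalization and no array scaling left 2 lists each, and 1 list was left without DKS-5 normoxia replicate 1, DKS-5 hypoxia replicate 2 or DKO-3 normoxia replicate 2, and 0 without DKO-3 hypoxia replicate 2, while the RNA quality covariate gave 6. Among the 64 genes past the threshold in DKS-5, 58 rose more there, as choosing them there favours, whereas among the 44 chosen in DKO-3, 25 rose more in DKS-5.

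The fourth comparison set the lines side by side in normoxia. DKS-5 lacked much of the signal of several genes that were bright in DKO-3. SH3BGRL was lower in DKS-5 by -4.53 ± 0.26 on the log2 scale (SE, 2 arrays per group; 6.67 ± 1.90 against 507 ± 23.0, SD, n = 2; adjusted p = 2.09e-07). The intestinal keratin gene KRT20 was 17.1-fold lower, the kinase gene RPS6KA6 13.6-fold, the immunoproteasome subunit gene PSMB9 11.6-fold, CADPS2 11.5-fold, HMGN5 9.64-fold, the stem cell marker gene PROM1 9.59-fold, KLHL13 9.46-fold, CELF2 8.49-fold and the calcitonin gene CALCA 7.96-fold, although CALCA stood at -0.60 (adjusted p = 0.711) with a pseudocount of 1. The brightest probe set is chosen anew for each pseudocount. A smaller pseudocount widens the difference of a given probe set, so the -0.60 belongs to another CALCA probe set. The order again depended on the pseudocount, because the signals of CADPS2, HMGN5, KLHL13 and CELF2 in DKS-5 averaged 0.722, 0.808, 0.824 and 1.95. With 1 in place of 16, CADPS2 stood at -6.69, HMGN5 at -6.34, KLHL13 at -6.30 and SH3BGRL at -6.07. Higher in DKS-5 were HHIP, an inhibitor of hedgehog signalling, by 3.64 ± 0.29 (410 ± 69.3 against 18.2 ± 5.97, SD, n = 2; adjusted p = 3.02e-06), C6orf141 (8.03-fold), the zinc finger gene BCL11A (7.91-fold), NIBAN1 (7.82-fold), the endoderm transcription factor gene FOXA2 (6.79-fold), ZNF182 (6.62-fold), the tryptophan dioxygenase gene TDO2 (5.73-fold), the phospholipase gene PLA2G4A (4.84-fold), SESTD1 (4.71-fold) and NPTX2 (4.50-fold). In all, 324 genes differed, 90 higher and 234 lower in DKS-5.

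The interferon response list was lower in DKS-5, with 4 of 13 genes past the threshold and 5 adjusted over the list alone. IFIT2 was at -2.20, IFIT1 at -1.89, IFIT3 at -1.70 and OAS2 at -1.17, all interferon-induced antiviral genes (camera adjusted p = 0.00321, and adjusted p = 0.485 with an estimated correlation). Other hypoxia-adaptation genes were lower too, with NDRG1 (-1.43) and DDIT4 (-0.65) past the threshold among 23 and 3 adjusted over the list alone (camera adjusted p = 0.0104, and adjusted p = 0.485 with an estimated correlation). Wnt/beta-catenin targets were higher, with TNFRSF19 (2.02) and the stem cell receptor gene LGR5 (1.49) past the threshold among 14 and 3 adjusted over the list alone (camera adjusted p = 0.00385, and adjusted p = 0.485 with an estimated correlation). Cholesterol synthesis was higher, with SC5D (1.29) past the threshold among 15 genes by either adjustment (camera adjusted p = 0.00321, and adjusted p = 0.485 with an estimated correlation). Ribosome biogenesis had a median of 0.20 over 17 genes with none past the threshold by either adjustment (camera adjusted p = 0.0389, and adjusted p = 0.686 with an estimated correlation). Fry called none of these 5 lists. Leaving out 1 of the 4 normoxia arrays ended the camera calls of other hypoxia-adaptation genes (1 array), cholesterol synthesis (2 arrays) and ribosome biogenesis (3 arrays), whereas those of the interferon response and Wnt/beta-catenin targets were kept.

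The remaining lists were not called by camera in normoxia. Of 12 intestinal differentiation genes, KRT20, TFF2 (-1.35) and REG4 (-1.45) were lower and VIL1 (1.77) was higher, although a dimmer VIL1 probe set gave -0.22 (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0752). Of 19 ERK pathway output genes, ETV1 (1.51) was higher, by either adjustment, and the list's camera adjusted p was 0.675. DUSP4 stood at -0.72 (adjusted p = 0.303). HK1 (0.96) was higher and ENO2 (-1.58) lower among 20 glycolysis genes (1 higher and 2 lower adjusted over the list alone; list median 0.05, mean -0.02). FGF2 (1.31) was higher among 11 angiogenic factors, and CLDN1 (-1.14) and KRT19 (-1.04) were lower among 17 epithelial genes, in each case by either adjustment. LCN2 (-1.71) was lower and PTGS2 (1.02) higher among 13 genes of NF-kappaB and chemokines, although a dimmer PTGS2 probe set gave -0.04. These too were the calls adjusted over the list alone. No gene passed in the lists of oxygen sensing, collagen modification, apoptosis regulators, EGFR ligands, proliferation, mesenchymal genes, stress response or oxidative phosphorylation, and adjusted over the list alone 1 EGFR ligand and 1 stress response gene were lower. HRAS was at 0.04 ± 0.30 and HIF1A at 0.38 ± 0.22 (SE), neither past the threshold. The count of 324 became 144 without the filter, and 127, 119, 146 and 161 without DKS-5 normoxia replicates 1 and 2 and DKO-3 normoxia replicates 1 and 2. The calls of HK1, FGF2, DDIT4, ETV1, LGR5, TFF2, REG4, CLDN1, KRT19, SC5D, LCN2, PTGS2 and OAS2 each ended without at least 1 of these 4 arrays (adjusted p between 0.0557 and 0.475), whereas those of NDRG1, ENO2, TNFRSF19, VIL1, IFIT1, IFIT2, IFIT3 and the largest differences did not. With the mean of all their probe sets ETV1 (0.61), VIL1 (0.75), REG4 (-0.77), KRT19 (-1.09) and PTGS2 (0.49) did not pass. The RNA quality covariate gave 261 genes, 228 of them among the 324. FGF2, DDIT4, REG4, KRT19 and OAS2 were among the genes whose calls ended with it.

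**Figure D3:**
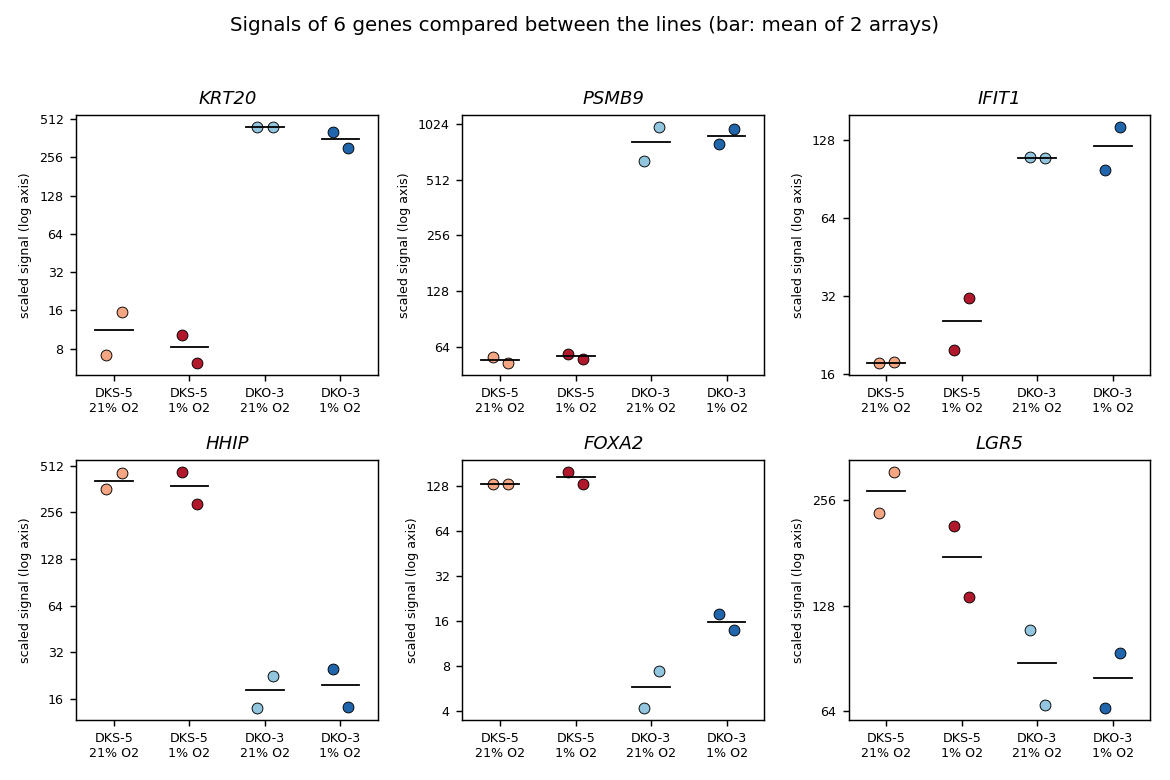
Scaled signal (log axis) of KRT20, PSMB9, IFIT1, HHIP, FOXA2 and LGR5 on each of the 8 arrays; points are arrays and lines are means of 2 arrays. PSMB9 averaged 54.3 and 56.9 in DKS-5 normoxia and hypoxia, and 815 and 876 in DKO-3 normoxia and hypoxia.

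The fifth comparison set the lines side by side in hypoxia. The largest differences were those of normoxia: SH3BGRL was lower in DKS-5 by -5.27 ± 0.26, KRT20 by -3.92, PSMB9 by -3.61, RPS6KA6 by -3.56 and KLHL13 by -3.38 (-5.91 with a pseudocount of 1, past KRT20 at -5.28), and HHIP was higher by 3.45 ± 0.29 (SE, 2 arrays per group; adjusted p = 5.02e-06). New among the 10 largest on either side were BAHCC1 (4.66-fold higher in DKS-5, although its other probe set gave 0.47) and the adaptor gene GRB10 (4.44-fold higher). VEGFA was 3.44-fold higher in DKS-5 in hypoxia (adjusted p = 0.000401), with its 4 probe sets between 0.06 and 1.78 on the log2 scale. In all, 557 genes differed, 177 higher and 380 lower in DKS-5. Between the oxygen levels, which share no arrays, 71 higher and 176 lower calls coincided, where independent lists would share 1.25 and 6.98. Both comparisons used the same spread estimate of each gene, which by itself favours calls in common.

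Angiogenic and vasoactive factors were higher in DKS-5 in hypoxia, with VEGFA, STC1 (1.46), ANGPTL4 (1.01) and FGF2 (1.07) past the threshold among 11 and 5 adjusted over the list alone (camera adjusted p = 0.0133, and adjusted p = 0.319 with an estimated correlation). Cholesterol synthesis was higher, with SC5D (1.64), SQLE (0.96), INSIG1 (0.93) and MSMO1 (0.87) past the threshold among 15 and 6 adjusted over the list alone (camera adjusted p = 5.91e-05, and adjusted p = 0.319 with an estimated correlation). A dimmer SQLE probe set gave -0.27. ERK pathway output was higher by camera, with ETV1 (2.04) and IER3 (0.93) higher and the ephrin receptor gene EPHA4 (-1.60) lower among 19 (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0205, and adjusted p = 0.423 with an estimated correlation). Wnt/beta-catenin targets were higher, with TNFRSF19 (1.97) past the threshold among 14 and 2 adjusted over the list alone (camera adjusted p = 0.0115, and adjusted p = 0.423 with an estimated correlation). Camera placed glycolysis higher, with ALDOC (1.05) past the threshold among 20 and 7 adjusted over the list alone (camera adjusted p = 0.0322, and adjusted p = 0.436 with an estimated correlation). Of the 20 genes 11 had positive values (mean 0.16), and the call was lost in 10 of 18 other settings, with adjusted p of up to 0.465, reached with quantile normalization. The interferon response was lower, with IFIT3 (-2.06), IFIT1 (-1.71) and IFIT2 (-1.69) past the threshold among 13 and 6 adjusted over the list alone (camera adjusted p = 5.91e-05, and adjusted p = 0.319 with an estimated correlation). Intestinal differentiation was lower, with KRT20, REG4 (-1.93) and TFF2 (-1.90) lower and VIL1 (1.53) higher among 12 (5 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00868, and adjusted p = 0.319 with an estimated correlation). The camera calls of angiogenic factors, ERK pathway output and Wnt/beta-catenin targets ended without DKO-3 hypoxia replicate 2 and without 1 DKS-5 hypoxia replicate, and fry did not call the ERK, Wnt and cholesterol lists. The call of intestinal differentiation ended with a pseudocount of 1.

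In lists that camera did not call in hypoxia, single members differed: PPFIA4 (-2.26), LCN2 (-2.01), BTC (-1.08), CLDN1 (-1.07), ASNS (-0.87) and ATF4 (-0.80) were lower in DKS-5, and TNFRSF10B (0.69), AURKA (0.57) and NPM1 (0.45) higher. Dimmer probe sets of ASNS (0.11), TNFRSF10B (-0.13) and AURKA (-0.29) went the other way, and without array scaling NPM1 stood at -0.0059. The lists of oxygen sensing, collagen modification, mesenchymal genes and oxidative phosphorylation had 0 members past the threshold. Adjusted over the list alone, the uncalled lists gave 1 higher and 1 lower gene each for other hypoxia-adaptation genes, collagen modification and apoptosis regulators, 1 lower EGFR ligand, 1 higher gene each for proliferation and ribosome biogenesis, 1 higher and 2 lower epithelial genes, and 1 higher and 4 lower genes each for the stress response and NF-kappaB and chemokines. Median and mean had opposite signs for other hypoxia-adaptation, epithelial and mesenchymal genes, and camera placed collagen modification and apoptosis regulators upward although their medians were negative. HIF1A was at 0.32 ± 0.22 and HRAS at -0.10 ± 0.30 (SE), neither past the threshold. This comparison is the one whose groups differed most in the ACTB 3' to 5' ratio, with 54.8 and 25.6 in DKS-5 hypoxia against 11.47 and 11.02 in DKO-3 hypoxia. With the RNA quality covariate 118 genes passed, 105 of them among the 557, and among list genes only KRT20, TFF2, IFIT3, ETV1, IER3, SC5D and PPFIA4 kept their calls. All 4 angiogenic factors lost theirs (VEGFA at 1.45, adjusted p = 0.0683; STC1 at 1.77, 0.084; ANGPTL4 at 1.22, 0.171; FGF2 at 0.82, 0.450), as did MSMO1, SQLE and INSIG1 of cholesterol synthesis, IFIT1 and IFIT2, TNFRSF19, ALDOC and BAHCC1. With the mean of all their probe sets VEGFA (0.73, adjusted p = 0.141), BAHCC1 (0.42, adjusted p = 0.247), ANGPTL4 (0.63), FGF2 (0.91), ETV1 (0.63), EPHA4 (-0.84), SQLE (0.37) and INSIG1 (0.74) did not pass, nor did BTC, ASNS, TNFRSF10B, AURKA and NPM1. CALCA, again through another probe set, stood at -0.58 with a pseudocount of 1. In absolute size the median log2 difference of the 557 was 1.14 without the covariate, and taken in the direction called it was 1.17 with it, and their median SE was 0.254 and 0.369. Without array scaling the median of all genes lay at -0.42 and the split of calls was 63 higher to 2320 lower, and the count was 217 without the filter, 357 in a fit of 4 arrays, 135 without DKO-3 hypoxia replicate 1 and 258 without DKO-3 hypoxia replicate 2. VEGFA, SC5D, ETV1, IER3, TFF2, VIL1, IFIT1 and IFIT3 kept their calls without either of these arrays. Without each of them in turn the calls of ALDOC (adjusted p = 0.239 and 0.0759), STC1, ANGPTL4, FGF2, SQLE, INSIG1, IFIT2, TNFRSF10B, BTC, AURKA, ATF4, ASNS and NPM1 ended. Those of EPHA4, CLDN1 and MSMO1 ended only without replicate 1, and that of REG4 only without replicate 2.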

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

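Camera with an estimated correlation was an alternative fixed beforehand, but reading it as a test of correlated genes within the lists was chosen after its result was seen, and the RNA quality covariate after the control probe sets were seen to differ between arrays. A test of the difference in hypoxia response between the lines (camera on the interaction) placed 4 fixed lists toward DKS-5: glycolysis at adjusted p = 0.0272, angiogenic and vasoactive factors at 0.0291, other hypoxia-adaptation genes at 0.00243 and ERK pathway output at 0.0291. None was kept with an estimated correlation (adjusted p = 0.606 for each). For angiogenic and vasoactive factors the estimated correlation was -0.0188, below the preset value, so correlated genes cannot account for that lost call. The loss of a call is thus by itself no evidence of correlation. The estimate was 0.0954 for glycolysis, 0.109 for other hypoxia-adaptation genes and 0.0985 for ERK pathway output. For the lists with these positive estimates, a part played by correlated genes is not decided, because lists with negative estimates lost calls too. For hypoxia in DKS-5, oxygen sensing and HIF feedback (estimate -0.0277) went from camera adjusted p = 0.000786 to 0.0754. ERK pathway output passed camera in neither line alone (medians 0.0024 and -0.14), and for glycolysis the median rise was 0.83 in DKS-5 against 1.07 in DKO-3 but the mean rise 1.12 against 0.94, with 13 of 20 genes larger in DKS-5 (median difference 0.34). Other hypoxia-adaptation genes differed between the lines mainly in normoxia (median -0.24, DKS-5 minus DKO-3) and little in hypoxia (0.0551).

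Over the 73 genes of these lists the median difference in log2 response was 0.16. With the RNA quality covariate it was 0.25 (95% bootstrap interval over genes 0.13 to 0.41), so the covariate did not lower it. The interval leaves out the spread between arrays, and the lists were chosen by their calls in these data. A part played by RNA quality is therefore not decided. The lowest median with 1 of the 8 arrays left out was 0.13. The sign of the median thus did not rest on a single array, although the camera calls of these lists ended without DKO-3 hypoxia replicate 2. A difference that comes with the K-ras genotype of the lines stays open and untested, since each genotype is represented by 1 line.

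Among 5734 probe sets without a gene name here that were bright enough to test, 1 rose with hypoxia in DKS-5 and 0 in DKO-3 (limma).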

How the results depend on the processing

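The RNA quality covariate, no array scaling and the closer look at the fit without DKS-5 hypoxia replicate 2 were chosen after the data were seen; the other alternatives were fixed before. The interaction kept 0 genes in every setting, at unadjusted p under 0.05 for 193 to 1551 genes. Of the values of named genes past the threshold, 43 of 500 for hypoxia in DKS-5, 73 of 417 in DKO-3, 83 of 827 for the lines in normoxia and 156 of 992 in hypoxia were no longer past it in a setting, and 1 reversed. For hypoxia in DKS-5 the 64 genes became 35 without the filter, 32 without array scaling and 36 in the fit of 4 arrays, with 29 to 294 when an array was left out. For hypoxia in DKO-3 the 44 became 7 without the filter, 8 with the covariate, 84 without array scaling and 68 in the fit of 4 arrays, with 1 to 69 when an array was left out. For the lines in normoxia the 324 became 144 without the filter, with 119 to 441 when an array was left out; in hypoxia the 557 became 217 without the filter, 118 with the covariate, 2383 without array scaling and 357 in the fit of 4 arrays, with 135 to 761. The overlap of 31 became 7 without the filter and 6 with the covariate, with 1 to 41. With the covariate the median SE of the called genes went from 0.255 to 0.334 for hypoxia in DKO-3 and from 0.254 to 0.369 for the lines in hypoxia, and their median log2 change, taken in the direction each gene was called, from 1.502 to 1.541 and from 1.14 to 1.17, while single genes moved further (VEGFA between the lines in hypoxia from 1.78 to 1.45). Without array scaling the median of all genes moved to -0.19 for hypoxia in DKS-5, 0.20 in DKO-3, -0.41 for the interaction and -0.42 for the lines in hypoxia; the cause of the other moves was not tested. With an estimated correlation, camera called 2, 0, 0, 0 and 0 lists in the 5 comparisons in place of 9, 5, 4, 5 and 7. Fry called 6 for hypoxia in DKS-5, 4 for hypoxia in DKO-3, 0 for the interaction, 0 for the lines in normoxia and 3 in hypoxia. For hypoxia in DKO-3 the 5 lists became 9 with a pseudocount of 64, 9 with the filter at the 60th percentile, 8 with quantile normalization, and 5 to 8 when an array was left out. The 4 interaction lists became 2 with quantile normalization and 2 without array scaling, and 0 to 6 when an array was left out. The 7 lists in hypoxia became 4 with the filter at the 60th percentile and 3 to 9 when an array was left out, the 5 in normoxia 3 to 5, and the 9 for hypoxia in DKS-5 8 to 9. Reversed signs concerned small values not past the threshold, apart from NPM1 between the lines in hypoxia (-0.0059 without array scaling). With the covariate HIF1A was at 0.0126 for hypoxia in DKO-3 and -0.27 for the lines in hypoxia (-0.13 without array scaling), and HRAS at -0.32 for hypoxia in DKO-3, 0.32 for the interaction and 0.69 for the lines in hypoxia; HRAS was at -0.0605 for hypoxia in DKS-5 without array scaling. With an array left out the values ran from -0.39 to 0.27 for HIF1A and -0.47 to 0.15 for EPAS1 in the interaction. For HRAS they ran from -0.0395 to 0.41 for hypoxia in DKS-5, -0.10 to 0.75 in DKO-3, -0.56 to 0.29 for the interaction, -0.39 to 0.46 for the lines in normoxia and -0.37 to 0.17 in hypoxia. Same-numbered arrays did not all deviate together (correlations of deviations from -0.0874 to 0.33 over the 6 pairs of groups, with 3 of the 6 over 0.1), and the labels name nothing that a number shares, so the number was not taken to pair samples. The highest values were those between the lines at the same oxygen level, 0.33 in hypoxia and 0.21 in normoxia. A pairing of same-numbered samples between the lines is thus not excluded. With the replicate number as a block the counts were 76, 92, 0, 455 and 791 genes, the overlap 43, and the lists 9, 9, 4, 6 and 6.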

Other observations

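The looks at antigen presentation genes and at X-linked genes, the scan over chromosomes and the test of a chance run of genes were chosen after the results were seen. PSMB9, among the largest falls in DKS-5, prompted a look at 18 genes of antigen presentation, 17 of them tested and PSMB9 included, so no test of the group is given. The class I gene HLA-B was at -1.26 in normoxia (adjusted p = 0.0133) and -1.19 in hypoxia (adjusted p = 0.0160), and NLRC5, which activates class I genes, at -1.61 (adjusted p = 0.00329) and -1.58 (adjusted p = 0.00319). HLA-C (-0.86, adjusted p = 0.0268) and B2M, the class I light chain (-0.70, adjusted p = 0.0346), were lower in normoxia, and did not pass in hypoxia (-0.62 and -0.41). B2M lies on chromosome 15 just before TRIM69, where the runs of lower genes described below begin. Its own run had a median of -0.04 in normoxia. Whether its lower value belongs to that shift was not tested. PSMB8 (-1.33, adjusted p = 0.00594) and HLA-DMB (-1.16, adjusted p = 0.0167) were lower in hypoxia, and did not pass in normoxia (-0.75 and -0.53). TAP1, at -0.86 and -0.70, and CD74, at -0.23 and -0.06, did not pass at either oxygen level.

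Chromosome X held 5 of the 20 largest falls in DKS-5 in normoxia, a count that was itself the reason to look, so no test is given. It held 14 of all 234 genes lower there and 3.09% of all genes tested, with a median of -0.01 over its 394 genes. The 5 were SH3BGRL, RPS6KA6, HMGN5, KLHL13 and PBDC1 (-2.73), and HEPH (-2.21) was lower too, while ZNF182 on the same chromosome was 6.62-fold higher.

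Genes of chromosome 15 were lower in DKS-5 than in DKO-3 along most of its length: the median over 428 genes was -0.28 in normoxia and none of its genes passed the threshold as higher, against 24 lower, while the medians of the other chromosomes lay between -0.03 and 0.09. In runs of neighbouring genes, up to 40 each and ordered by assembly GRCh38.p14, 9 of 320 had a median under -0.25 at both oxygen levels, 8 of them on chromosome 15 from TRIM69 to its end at TARS3 and 1 on chromosome 11 from CLMP to ST14. The median of chromosome 15 was -0.28 with the RNA quality covariate (95% bootstrap interval over genes -0.31 to -0.23). This argues against RNA quality, although the interval leaves out the spread between arrays. Relative to all genes the median was -0.28 with quantile normalization. Scaling moves the genes of an array together, so a value relative to all genes could hardly change and does not test array scaling. Against 10000 random lists of genes matched on mean expression the p was 1e-04. This was the smallest possible with that many lists, before any allowance for the 23 chromosomes scanned. Genes were drawn and no arrays were permuted, so the p leaves out the spread between arrays. The chromosome was picked from the same values, so the p is no independent test. A lower DNA copy number of most of chromosome 15 in DKS-5 may underlie this shift; DNA was not analysed here, so this is a hypothesis from the same data.

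Whether genes chosen in DKO-3 rose further in DKS-5 was tested as a sign of a larger response in DKS-5, since choosing them in DKO-3 works against it. The median difference over these 44 genes was 0.0498 (95% bootstrap interval over genes -0.19 to 0.28), with 25 larger in DKS-5. The interval holds values on both sides of 0, so a generally larger response in DKS-5 and an equal one cannot be told apart.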
